A study of Mus musculus with 6 samples.

How the data were processed

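Enhanced reduced representation bisulfite sequencing (ERRBS) reads the methylation of cytosines in CpG dinucleotides within size-selected restriction fragments, a sample of the genome rich in CpG-dense DNA. Bisulfite converts unmethylated cytosines, which are then read as T, while 5-methylcytosine and 5-hydroxymethylcytosine are both read as C and cannot be separated by this assay. The samples were naive B cells from mouse spleens, 3 from Tet2 knockout (KO) mice and 3 from wild-type (WT) mice, all of the strain C57BL/6 per the labels. The design text of the series names germinal centre B cells, whereas its title and the labels of all 6 samples name naive B cells, and the sample labels were followed here. Whether each library came from a separate mouse is not given in the labels, so p-values measure the spread between these libraries, part of which may be technical.

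Reads were processed with Bismark on the genome build GRCm38, per the submitters' processing notes; the Bismark version, trimming and duplicate handling are not given in the sources used here. Each library has its own table, per the file headers in the column layout of methylKit, with 1 line per CpG cytosine and strand. The deposited coverage is a raw read count per cytosine, without normalization, and no cytosine has a count below 10. The deposited methylation values are the percent of covering reads with C and the percent with T, per the file headers. Read counts with C and T were recovered as percent times coverage, and 100% of values came out whole within the rounding of the last decimal of the percent. Between 0.0178% and 0.0190% of reads per library carried another base and were left out. Reads come from PCR without molecular identifiers, so binomial precision covers counting error only, and the tests below take their error from the spread between libraries.

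Gene positions came from the RefSeq gene table of GRCm38.p6, with 21887 protein-coding genes. The table gives gene spans without strand or exons, and no genome sequence was used. Promoters were therefore replaced by windows of 1 kb on each side of both gene ends ("lower" and "upper" end by coordinate), and gene bodies by gene interiors, the span without 1 kb at each end. Exon, intron and CpG island context and sequence motifs were not analysed here. Context was described instead by the methylation level, by the number of measured cytosines within 250 bp, and by position relative to protein-coding genes.

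Differences were tested with a quasi-binomial model on the C and T counts, with 1 methylation level per genotype. The overdispersion per feature (4 residual degrees of freedom) was moderated across features by the empirical Bayes method of limma and held at 1 or above, an F test compared KO with WT, and p-values were adjusted by the Benjamini-Hochberg method. A feature was called at an adjusted p under 0.05 and a difference of pooled methylation of at least 10 percentage points. Features were single cytosines, 1 kb tiles with at least 3 cytosines, gene-end windows with at least 3 and gene interiors with at least 5, each over cytosines covered at least 10 times in all 6 libraries. Values are given as mean ± SD over the n = 3 libraries of a genotype, and differences as KO minus WT of the pooled reads. Library means were compared with a two-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Shares of tiles were compared with two-sided Fisher's exact tests, adjusted over the 20 tests made.

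Before the data were examined, 17 gene lists were fixed: B cell identity, naive B cell quiescence and trafficking, germinal centre program, plasma cell differentiation, B cell receptor signalling, antigen presentation and costimulation, NF-kB and Toll-like receptor signalling, lymphoma tumour suppressors and cell cycle inhibitors, DNA methylation machinery, T cell, myeloid, NK cell and erythroid markers, imprinted genes, Hox and developmental transcription factors, germline genes, and clustered protocadherins. Of the 397 entries, 388 matched a protein-coding gene. Lists were tested with camera (preset correlation 0.01, and estimated correlation) and fry in limma on log2((C + 2)/(T + 2)), for windows and for interiors. The rule for named genes was also fixed then: Tet2 first; the 5 largest gains and losses among called tiles, windows and interiors with complete separation of the genotypes; the 3 largest gains and losses among called cytosines; the 5 genes with most called cytosines per direction; and from each list the called members up to 4, or the member with the smallest p. Other genes named were chosen after their values were seen, and are said to be. Some results that this rule or the smallest p would name are not reported here.

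The alternatives were a coverage minimum of 20, an upper limit at the 99.9th percentile of coverage, autosomes alone, each library left out in turn, the replicate number as a block, no moderation of the overdispersion, Fisher's exact test on pooled counts, minimum differences of 25 points and of none, other tile sizes, summed strands, equal weights for the cytosines of a region (chosen after seeing the data), edgeR's quasi-likelihood test and limma on the log2 ratios. Tests were run in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Numba 0.67.0, and in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1; Matplotlib 3.10.9 drew the plots. The tests were checked on simulated data in which 50 features of each size were shifted by 10, 20, 30 or 40 points. The overdispersion of each simulated feature was drawn from the distribution that the moderated model had fitted, and libraries were simulated independently. The simulation therefore favours the moderated model over the other tests. Its shares of recovered shifts and false calls hold for data of that kind, without outlying libraries or inherited segments. Among 108462 simulated tiles the quasi-binomial model recovered 4%, 64%, 84% and 100% of these shifts, and 1.56% of its calls were false. It recovered 20%, 80%, 92% and 98% among 17511 gene-end windows and 30%, 82%, 92% and 98% among 11303 gene interiors. Among 991059 simulated cytosines it recovered 0%, 2%, 22% and 44%, and 17.1% of its calls were false. In the simulated tiles edgeR recovered 0%, 0%, 10% and 38% and limma 0% at each size.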

Results

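ERRBS profiles of splenic naive B cells, the resting mature cells from which germinal centre responses start, were compared between 3 Tet2 KO and 3 WT libraries. TET2 is a dioxygenase that oxidises 5-methylcytosine, a step of DNA demethylation, and the comparison addressed how its loss changes DNA methylation in these cells. Each library held between 1551481 and 1626375 CpG cytosines, with a median coverage between 92 and 110 reads per cytosine and between 168455105 and 207065050 reads over all cytosines. In all 6 libraries together, 1457048 cytosines were measured. Across these cytosines, which are not independent replicates, pairs of libraries correlated with Pearson's r between 0.985 and 0.991.

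Within Tet2 itself (gene 214133, chromosome 3, 133463677 to 133545136, GRCm38), the KO libraries lacked coverage over 1 stretch that every WT library covered. Its 6 cytosines, from 133486189 to 133486297, had between 28 and 71 reads in each WT library, with mean coverage of 55.2, 57.2 and 45.2 reads in WT 1, WT 2 and WT 3. None of them reached 10 reads in KO 1, KO 2 or KO 3, which places KO coverage below 17.1% of the WT mean. On either side, the nearest cytosines measured in the KO libraries lay at 133468161 and 133533475. Outside this stretch, 111 cytosines of Tet2 and its flanks of 1 kb were measured in all 6 libraries. The 96 at the upper end of Tet2 were unmethylated in both genotypes, at 0.139% ± 0.0596 in KO and 0.0968% ± 0.00660 in WT (n = 3 each), and the other 15 were highly methylated, at 97.3% ± 0.966 and 96.6% ± 0.796.

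**Figure D1:**
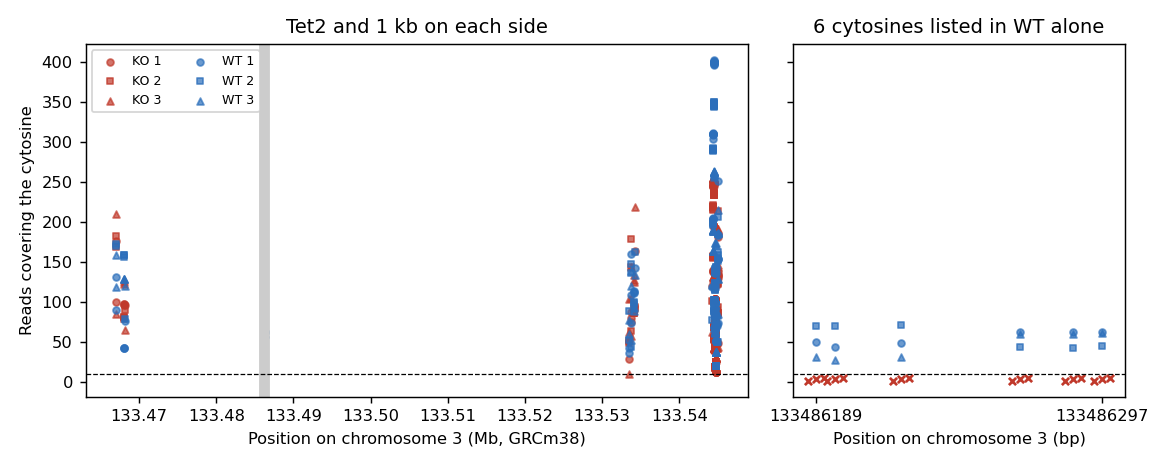
Reads covering each measured cytosine of Tet2 and 1 kb on each side, by position on chromosome 3 and library (left), and the same for the shaded 6 cytosines listed in WT libraries alone (right); the dashed line marks the minimum of 10 reads and crosses mark KO values under it, drawn without their unknown height. The 6 cytosines carry 28 to 71 reads in the WT libraries and fewer than 10 in all KO libraries.

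Across the genome, methylation was higher in KO at cytosines of intermediate methylation, while cytosines that were unmethylated in WT stayed near 0% in both genotypes. Cytosines at 30 to 70% in WT averaged 54.7% ± 0.662 in KO and 51.4% ± 1.83 in WT, a difference of 3.30 percentage points. Those at 70 to 90% averaged 86.2% ± 0.381 and 83.3% ± 1.24, and those at 10 to 30% averaged 19.1% ± 0.387 and 17.9% ± 0.496. The 883285 cytosines below 10% differed by 0.149 points. Regions of sparse CpGs, with 1 to 4 measured cytosines within 250 bp, differed by 0.749 points, and dense regions with 30 or more by 0.0652 points. Gene interiors differed by 0.522 points, DNA outside protein-coding genes by 0.569 points and DNA within 1 kb of a gene end by 0.117 points.

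Over all 1457048 cytosines, mean methylation was 33.7% ± 0.112 in KO and 33.4% ± 0.112 in WT, a difference of 0.344 points. In this mean and in each group of cytosines above, all 3 KO libraries lay above all 3 WT libraries, for which the exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. The class at 90 to 100% in WT was lower in KO by -0.441 points, and higher by 0.297 points when classes were set by the mean of all 6 libraries. That choice also gave 1.29 instead of 2.87 points at 70 to 90%, 2.72 at 30 to 70% and 0.0653 below 10%. WT 1 had the lowest value of the 30 to 70% class, 49.3%, and without it the difference in that class was 2.63 points and that at 10 to 30% was 0.724 points. Weighted by reads rather than by cytosine, the means were 27.4% ± 1.26 and 22.5% ± 2.21, since cytosines below 10% took 64.0% ± 1.60 of the reads in KO and 69.2% ± 2.24 in WT.

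**Figure D2:**
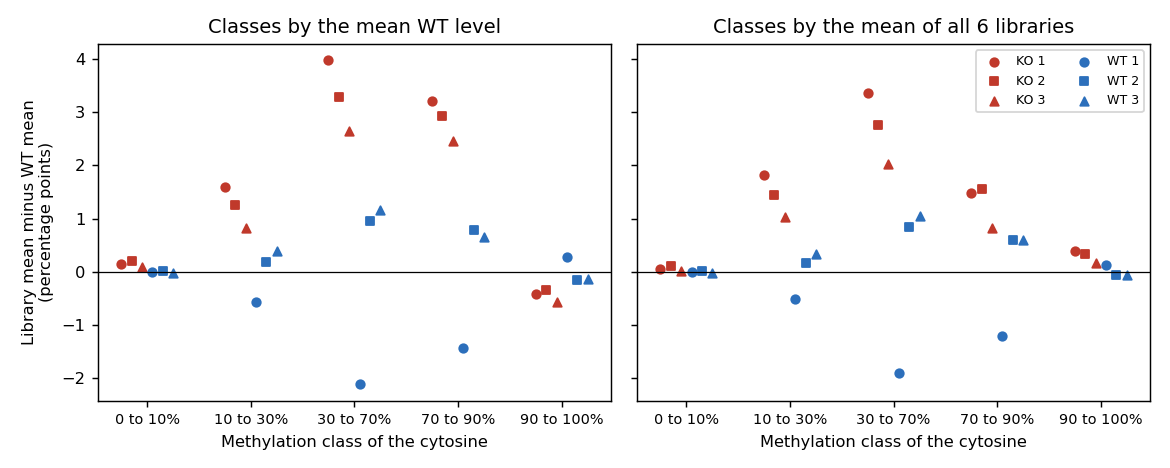
Library means relative to the WT mean, in percentage points, for classes of cytosines set by their mean WT methylation (left) or by the mean over all 6 libraries (right); each point is a library. At 30 to 70% the KO libraries lie above the WT libraries under both class definitions, and at 90 to 100% they lie below under the first and above under the second.

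Of the 108802 tiles of 1 kb tested, 122 gained methylation in KO and 0 lost it. The largest gain lay in Wipf1, which encodes a regulator of actin assembly that binds the WASP protein. There, 9 cytosines on chromosome 2 from 73454001 to 73455000 stood at 72.6% ± 4.57 in KO and 33.1% ± 8.61 in WT (difference 38.3 points, adjusted p = 0.00575). In Creb3l2, a membrane-bound transcription factor of secretory cells and a member of the plasma cell list, the tile on chromosome 6 from 37428001 to 37429000 rose from 33.4% ± 6.25 to 68.3% ± 3.72 (35.5 points, adjusted p = 0.00624). A tile 8.85 kb from Il10, the gene of an anti-inflammatory cytokine, rose from 44.5% ± 4.09 to 80.8% ± 11.5 (34.1 points, chromosome 1, 131010001 to 131011000, adjusted p = 0.0159). A tile 57.3 kb from Cryaa, which encodes a lens crystallin, rose from 37.1% ± 10.9 to 75.4% ± 6.97 (34.7 points, chromosome 17, 31739001 to 31740000, adjusted p = 0.0161).

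Yeats4, which encodes a reader of acylated histones in chromatin-modifying complexes, gained methylation at its lower end. There, 19 cytosines (tile on chromosome 10, 117215001 to 117216000) rose from 13.0% ± 7.81 to 46.7% ± 6.41, by 34 points (adjusted p = 0.00575). Genes of the fixed lists that gained a tile were, besides Creb3l2, Ebf1 and H2-Oa. Ebf1, the transcription factor that commits progenitors to the B lineage, rose within the gene from 61.2% ± 9.0 to 86.7% ± 2.13 (24.8 points, chromosome 11, 44887001 to 44888000, adjusted p = 0.0347). H2-Oa, part of the complex that restrains peptide loading on MHC class II, rose from 20.8% ± 6.36 to 38.9% ± 4.19 (17.6 points, chromosome 17, 34094001 to 34095000, adjusted p = 0.0215).

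**Figure D3:**
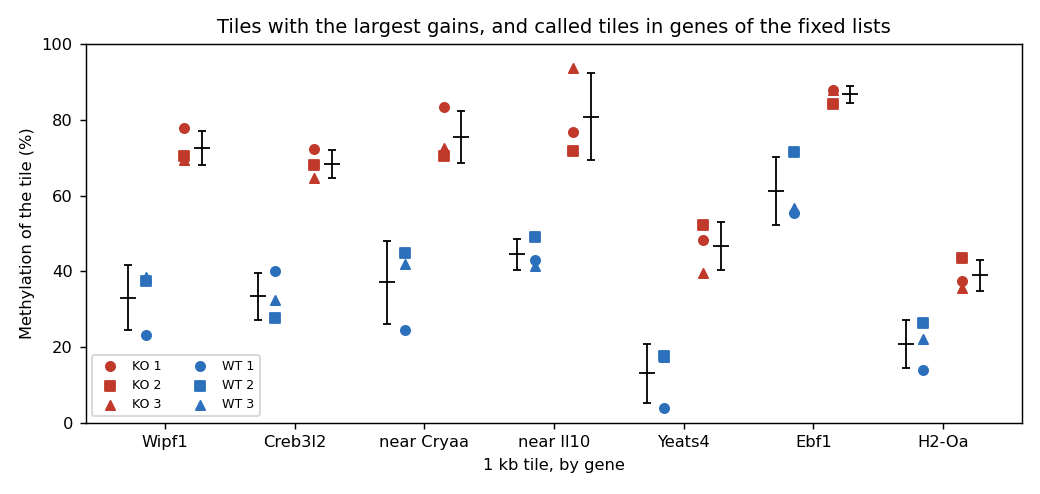
Methylation, in percent, of the 5 tiles with the largest gains and of the called tiles in Ebf1 and H2-Oa, with a point per library and the mean and SD of 3 libraries per genotype beside them. In each of these tiles all KO libraries lie above all WT libraries.

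Further genes among the gained tiles are named here, chosen after their values were seen. A tile 27.0 kb from Bach1, a haem-regulated repressor, rose from 20.1% ± 1.55 to 42.6% ± 4.62 (adjusted p = 0.00145). Cbfa2t3, a transcriptional corepressor of haematopoiesis, gained 31.1 points, Trib1, a pseudokinase that directs degradation of C/EBP factors, gained 28.9 points, and a tile 20.3 kb from Irf8, a transcription factor of B and myeloid cells, gained 26.3 points. Nod2, a sensor of bacterial peptidoglycan, gained 15.8 points. Rasgrp2, which activates the small GTPase Rap, gained 16.4 points.

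The gained tiles stood mostly at intermediate methylation in WT, with a median of 45.0%, and their median gain was 18.5 points (range 10.1 to 38.3). Of the 122, 78 had a WT level of 30 to 70%, a class that held 8.51% of tested tiles (odds ratio 19.2, Fisher's exact adjusted p = 3.71e-51). Tiles near 100% have no room for a gain of 10 points, and among the 56707 tiles below 90% in WT the odds ratio was 9.15 (Fisher's exact p = 4.83e-32). With levels taken as the mean of all 6 libraries the class held 71 gained tiles, with an odds ratio of 7.19 among tiles below 90%. Gene interiors held 66 (odds ratio 1.60, Fisher's exact adjusted p = 0.0136) and DNA within 1 kb of a gene end held 13 (odds ratio 0.381, Fisher's exact adjusted p = 0.000703). Among tiles at 10 to 90% methylation the odds ratio for gene ends was 0.699 (Fisher's exact adjusted p = 0.302) and that for interiors 1.61 (Fisher's exact adjusted p = 0.0136). Gained tiles lay on 18 chromosomes, with 0 of 3273 tiles on chromosome 18 and 0 of 2250 on chromosome X.

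**Figure D4:**
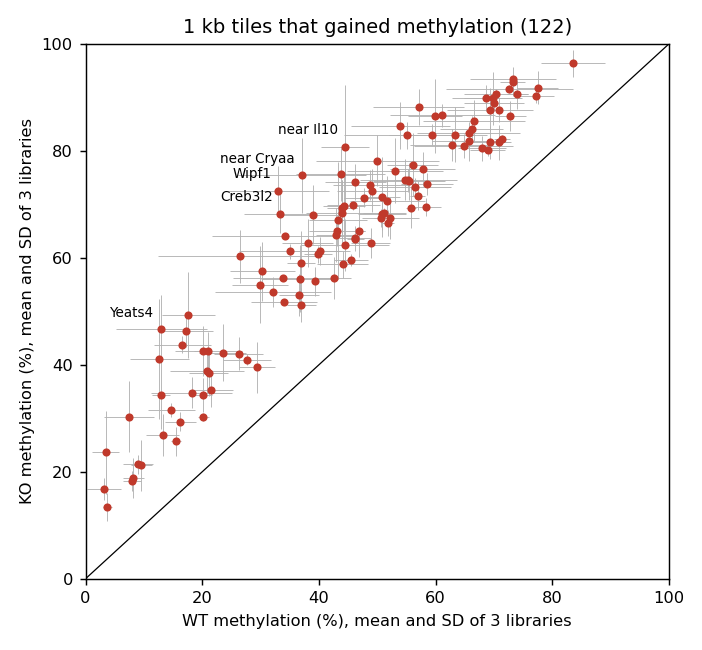
Methylation of the 122 gained tiles in WT (horizontal axis, percent) and KO (vertical axis, percent), as mean and SD of 3 libraries each, with the line of equal values. The tiles with the 5 largest gains are labelled with the gene they overlap or lie nearest to.

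Of all tested tiles, 11.7% separated the genotypes completely, against 10% by chance. At an unadjusted p under 0.05, 6247 tiles were higher and 1591 lower in KO. Without moderation of the overdispersion 0 tiles were called, edgeR called 0 (4539 higher and 1542 lower at an unadjusted p under 0.05) and limma 0 (5511 and 1640), although 122 and 121 of the 122 tiles had an unadjusted p under 0.05 there. Leaving out KO 2, WT 1 or WT 3 gave 52, 52 and 79 called tiles, with 49, 48 and 68 of the 122 among them, and leaving out KO 1 gave 82 gains, 67 of them shared, and 7 losses. With each cytosine weighted equally 84 tiles gained and 0 lost, 74 of them among the 122, and Ebf1 was not called (adjusted p = 0.0594). The tile near Il10 lost its call without KO 1, WT 1 or WT 3 and that near Cryaa without WT 3.

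Around gene ends, Yeats4 was the sole gene called among 17584 windows, and of 11315 gene interiors none was called. The Yeats4 window (117214141 to 117216141) holds the cytosines of its tile, and its gain of 34 points had an adjusted p of 0.0204. Within gene interiors small differences leaned towards KO: 1710 were higher and 56 lower at an unadjusted p under 0.05 by the quasi-binomial model, with 1537 and 80 by edgeR and 1281 and 120 by limma, which called 0 each. Complete separation was seen in 20.6% of interiors, against 10% by chance. Part of this lean came from pooling reads: with each cytosine weighted equally 1127 were higher and 133 lower, the median difference was 0.380 points instead of 0.897, and 16.9% separated. Of the 1710 interiors, 1491 stayed higher with equal weights, but only 479 of them kept an unadjusted p under 0.05. Interiors named below are given by pooled reads, and Vav1 also by equal weights. Without WT 3 the model called 78 interiors, 77 of them gains, and without KO 1 or KO 2, or with equal weights (adjusted p = 0.118), the Yeats4 window was not called. With equal weights the lower end of Dgkg, a diacylglycerol kinase, was called in its place, at 10.9 points (adjusted p = 0.0482). For windows, edgeR and limma called 0 (689 higher and 202 lower, and 786 and 218, at an unadjusted p under 0.05).

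Among genes of the B lineage, no list had a called window or interior, and members named here as values had the smallest p of their list. All tested windows and interiors also leaned higher in KO, with median differences of 0.0623 and 0.897 points. Counts of members higher in KO, here and below, are therefore not by themselves particular to a list. In the B cell identity list, 10 of 14 windows and 10 of 11 interiors were higher in KO. The interior of Pax5, the guardian of B cell identity, stood at 31.5% ± 1.77 in KO and 26.3% ± 2.70 in WT (adjusted p = 0.184), and the lower end of Spib, an ETS transcription factor, at 27.8% ± 1.80 and 21.1% ± 3.18 (adjusted p = 0.789). In the list of naive B cell quiescence and trafficking, 9 of 11 windows and 12 of 13 interiors were higher. The upper end of Klf2, a quiescence factor, stood at 26.6% ± 1.72 and 17.2% ± 4.91 (adjusted p = 0.402), and the interior of Cxcr5, the receptor that guides B cells into follicles, at 90.5% ± 0.571 and 80.4% ± 6.48 (adjusted p = 0.175). Adjusted over the list alone, the Klf2 window and 3 tiles, in Cxcr5, Foxp1 and Klf2, passed with differences of 10.8, 17.2 and 10.2 points in these tiles. Over all tiles their adjusted p was 0.0681, 0.0795 and 0.0845, so none of the 3 was called. Adjustment over a list alone, here and below, does not correct for the number of lists.

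In the germinal centre program, 11 of 19 windows and 11 of 16 interiors were higher, and adjusted over the list alone 2 tiles passed. They lay in Tnfrsf13c, the receptor of the survival factor BAFF (22.4 points, adjusted p = 0.124 over all tiles), and in Ccnd3, a cyclin of dividing B cells (17.5 points, adjusted p = 0.163). The Ccnd3 interior, which passed over the list without the minimum difference, stood at 39.5% ± 1.60 and 31.8% ± 1.68 (adjusted p = 0.150). Tnfrsf13c stood at its upper end at 0.0155% ± 0.0269 and 0.296% ± 0.238 (adjusted p = 0.840). In plasma cell differentiation, 7 of 13 windows and 9 of 12 interiors were higher. Adjusted over the list alone, the Creb3l2 tile and the lower end of Tnfrsf13b, a receptor of BAFF and APRIL, passed, the latter at 60.5% ± 4.26 and 49.7% ± 1.17 (adjusted p = 0.637 over all windows). The interior of Prdm1, the master regulator of plasma cells and also in the tumour suppressor list, stood at 54.1% ± 1.81 and 49.4% ± 0.693 (adjusted p = 0.155).

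No signalling list had a called window or interior. In B cell receptor signalling, 11 of 17 windows and 13 of 17 interiors were higher, and 1 interior passed when adjusted over the list alone, that of Vav1, an exchange factor below the receptor. Its pooled methylation was 33.9% ± 3.48 in KO and 53.8% ± 4.41 in WT (adjusted p = 0.150 over all interiors), while the mean over its 33 cytosines, each weighted equally, was 76.1% ± 0.535 and 76.4% ± 0.491. The lower end of Lyn, a kinase of the same pathway, stood at 0.421% ± 0.534 and 0.0792% ± 0.0397 (adjusted p = 0.836). In antigen presentation and costimulation, 6 of 10 windows and 6 of 8 interiors were higher. Adjusted over the list alone, the tile and the upper end of H2-Oa passed, the latter at 53.9% ± 5.02 and 39.3% ± 6.63 (adjusted p = 0.294 over all windows), and the interior of H2-Ab1, an MHC class II chain, stood at 1.33% ± 0.150 and 0.827% ± 0.165 (adjusted p = 0.197).

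In NF-kB and Toll-like receptor signalling, 14 of 20 windows and 12 of 12 interiors were higher and 0 passed adjusted over the list alone. The upper end of Nfkb1, an NF-kB subunit, stood at 1.33% ± 0.423 and 1.0% ± 0.105 (adjusted p = 0.850) and the interior of Myd88, a Toll-like receptor adaptor, at 96.7% ± 0.645 and 95% ± 0.818 (adjusted p = 0.304). Among lymphoma tumour suppressors and cell cycle inhibitors, 16 of 24 windows and 10 of 13 interiors were higher and 0 passed adjusted over the list alone. The lower end of Cdkn1c, an imprinted cell cycle inhibitor, stood at 36.1% ± 0.836 and 42.9% ± 3.10 (adjusted p = 0.578). Among genes of the DNA methylation machinery, 11 of 19 windows and 13 of 15 interiors were higher and 0 passed adjusted over the list alone. The interior of Tet1, a paralogue of Tet2, stood at 36.0% ± 2.23 and 28.5% ± 3.27 (adjusted p = 0.172), and the upper end of Tet3 at 0.163% ± 0.111 and 0.0756% ± 0.0178 (adjusted p = 0.867).

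Markers of other blood lineages showed no called window or interior. T cell markers were higher in 9 of 13 windows and 9 of 10 interiors. Adjusted over the list alone, the lower end of Zap70, a T cell receptor kinase, passed at 93.4% ± 2.45 and 82.6% ± 5.77 (adjusted p = 0.666 over all windows), and the upper end of Tcf7 passed without the minimum difference. The interior of Gata3, a T helper cell factor, stood at 15% ± 1.31 and 13.0% ± 0.833 (adjusted p = 0.227). Myeloid markers were higher in 4 of 6 windows and 4 of 8 interiors. NK cell markers were higher in 3 of 5 windows and 1 of 4 interiors. The lower end of Tbx21, a T-box factor, stood at 16.8% ± 4.75 and 7.81% ± 1.64 (adjusted p = 0.768) and the interior of Prf1, the perforin gene, at 90% ± 1.49 and 92.0% ± 2.23 (adjusted p = 0.722). Erythroid markers were higher in 5 of 9 windows and 4 of 7 interiors. The upper end of Slc4a1, an anion exchanger of red cells, stood at 35.5% ± 3.99 and 48.5% ± 4.80 (adjusted p = 0.850) and the interior of Ank1, a membrane skeleton gene, at 44.2% ± 0.941 and 37.4% ± 1.48 (adjusted p = 0.150). Myeloid and NK cell markers had 0 windows or interiors that passed adjusted over the list alone, and Ank1 passed there without the minimum difference, at 6.85 points.

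Imprinted genes, whose parental alleles carry opposite methylation, were higher in 13 of 18 windows and 12 of 16 interiors. The lower end of Nnat stood at 29.4% ± 0.230 in KO and 36.2% ± 1.56 in WT (adjusted p = 0.294), passing over the list alone without the minimum difference, and the interior of Inpp5f at 42.3% ± 4.32 and 34.4% ± 3.70 (adjusted p = 0.264). Hox and developmental transcription factors were higher in 51 of 79 windows and 31 of 43 interiors. Hoxd4 stood at its lower end at 32.9% ± 3.74 and 40.2% ± 2.46 (adjusted p = 0.771) and the interior of Pax2 at 10.3% ± 0.899 and 8.25% ± 0.957 (adjusted p = 0.186). Germline genes were higher in 9 of 20 windows and 9 of 11 interiors. Rnf17, a germ cell gene, stood at its lower end at 76.6% ± 7.11 and 81.1% ± 2.65 (adjusted p = 0.850) and the interior of Tex15, a piRNA pathway gene, at 62.5% ± 3.13 and 50.4% ± 6.37 (adjusted p = 0.187). Clustered protocadherins, neuronal adhesion genes, were higher in 37 of 51 windows and 35 of 40 interiors. Genes of these clusters overlap, so the same cytosines can enter these counts more than once, and the counts are not of separate regions. The lower end of Pcdhb1 stood at 44.0% ± 3.13 and 33.0% ± 4.45 (adjusted p = 0.484) and the interior of Pcdha12, which overlaps its neighbours, at 23.9% ± 0.587 and 20.6% ± 1.16 (adjusted p = 0.150). Adjusted over the list alone, 0 Hox or germline features passed, while 1 protocadherin tile passed, and 10 overlapping interiors of the alpha cluster passed without the minimum difference.

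No list was called by camera, which compares a list with all other regions, in 34 tests over windows and interiors (smallest adjusted p = 0.507; adjusted p = 0.982 with an estimated correlation), with 3 at an unadjusted p under 0.05. Called tiles were not over-represented in any list (Fisher's exact adjusted p = 0.602 for the lists of Ebf1, Creb3l2 and H2-Oa). By fry, which tests whether a list moves one way, 32 tests pointed up and 2 down and 0 were called (smallest adjusted p = 0.154; 7 unadjusted), though 2 were without KO 1. The median difference of a list was above 0 in 32 of the 34 tests, in 15 of which camera pointed down, since other regions were higher as well. Fry's test for changes in either direction called 4: the windows of the naive B cell list, and the interiors of the germinal centre, B cell receptor and antigen presentation lists (adjusted p = 0.0318 each). On simulated data, however, it also called 10 of 32 unshifted lists, and without any 1 of the libraries it called between 0 and 3.

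At single cytosines, 8 of 1095119 were called higher in KO and 0 lower, and 7 of the 8 lay on chromosome 1 between 85862281 and 98889701. The 30 measured cytosines within 200 bp of these 7 stood at 96.2% in WT and 95.1% in KO. A difference in sequence between the mice is a candidate explanation for the 7, taken up below, so they are not read as gains due to the loss of TET2. The largest difference was in Lrrfip1, which encodes a nucleic acid-binding regulator of transcription. Both strands of 1 CpG, at 91032631 and 91032632, stood at 61.6% ± 3.61 and 54.6% ± 11.4 in KO and at 0% in every WT library (60.9 and 54.9 points, adjusted p = 0.0305 and 0.0417). At 98889701, 373 kb from Slco6d1, the values were 60.1% ± 11.5 and 0% (59.0 points, adjusted p = 0.0305). Lrrfip1 held 3 called cytosines. The single call elsewhere was in Tmem143 (chromosome 7, 45909252), which rose from 8.88% ± 1.29 to 42.0% ± 1.77, by 33.0 points (adjusted p = 0.0397), within a tile that gained 20.9 points.

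The calls rested on a mean coverage between 61.2 and 170 reads per library and cytosine. At an unadjusted p under 0.05, 58176 cytosines were higher and 34716 lower. Without the stretch of chromosome 1 from 80 to 110 Mb 0 cytosines were called, as was the case without WT 1, WT 2 or WT 3, or without moderation. Without KO 1, 32 were called, 21 of them gains, and without KO 2 or KO 3 22 and 20, all gains.

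**Figure D5:**
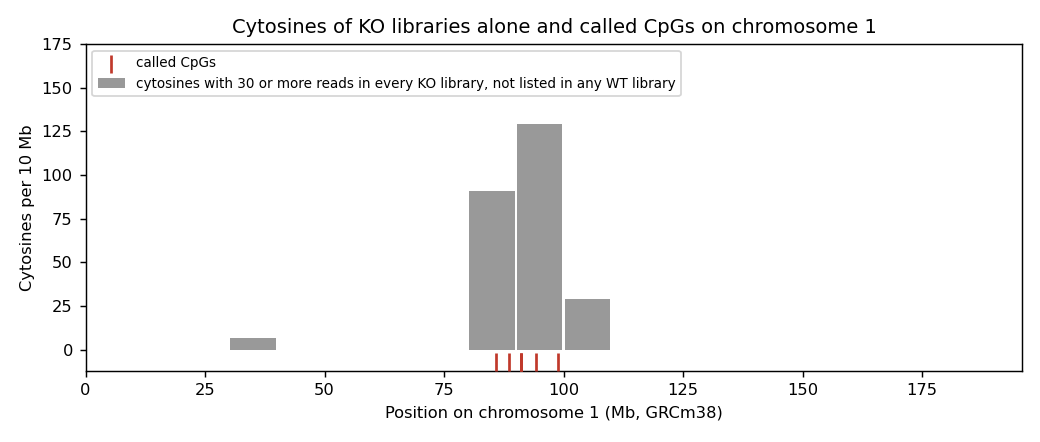
Cytosines along chromosome 1 that have 30 or more reads in every KO library and are not listed in any WT library, per 10 Mb (bars), with the positions of the called cytosines of chromosome 1 (ticks). Both sets lie between 80 and 110 Mb, apart from 7 cytosines between 30 and 40 Mb.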

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

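The tests in this part were chosen after the results they weigh were seen. Outside the comparison of methylation levels, coverage itself differed between the genotypes: 263 cytosines had at least 30 reads in all 3 KO libraries and were not listed in any WT library, and 249 of them (94.7%) lay on chromosome 1 from 80597584 to 105881834. They were picked out because this signal lies in cytosines that the comparisons above do not use. In the opposite direction, 13 cytosines had at least 30 reads in all 3 WT libraries and were not listed in any KO library, 5 of them on chromosome 3 from 130 to 140 Mb, where Tet2 lies.

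The called cytosines of chromosome 1 fall in the same stretch, so a candidate explanation is a segment of DNA that differs in sequence between these KO and WT mice, where a base change creates or removes a CpG. The 7 called cytosines had a median difference of 53.2 points, whereas the 30 measured cytosines within 200 bp of them had a median difference of -0.489 points and stood at 96.2% in WT and 95.1% in KO. Neighbours at this level have no room to gain, so the -0.489 decides nothing by itself. A gain across the stretch is argued against by its 80 tiles at 30 to 70% methylation, with a median difference of 1.99 points (quartiles -1.59 to 5.88) and 1.52 points in such tiles elsewhere. Cytosines at 25 to 75% in every KO library and under 8% in every WT library numbered 15 of 12154 there and 5 of 1444894 elsewhere. The stretch and the pattern were taken from the 7 called cytosines, which are among the 15, so no test of this excess is given. The opposite pattern, 25 to 75% in every KO library and over 88% in every WT library, was met by 1 cytosine there and 8 elsewhere. The 15 may reflect variants on 1 chromosome copy of 2 or a gain at these sites alone.

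A second structure cuts across the genotypes: comparing KO 1, WT 1 and WT 2 with the other 3 libraries called 39 cytosines, against 8 for KO and WT. Cytosines with at least 30 reads in every library of 1 set and not listed in the other numbered 189. KO 1, WT 1 and WT 2 had 107 of them, with 79 on chromosome 5 from 20 to 30 Mb, and the other set had 82. The 189 lay in 23 of the 285 bins of 10 Mb that held any cytosine. Their 20 fullest bins held 98.4% of them, a share that 23 bins nearly fix. The 20 fullest bins of all cytosines held 19.3% of those, which is not a like comparison. Counting cytosines within 300 bp of each other once, 96.6% of 88 fragments lay in their 20 fullest bins. In 1000 random draws of 88 fragments this share was 40.7% on average and at most 50%. Such clustering is consistent with inherited segments that differ between mice irrespective of Tet2.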

How the results depend on the processing

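Leaving out 80 to 110 Mb of chromosome 1, equal depth (each cytosine thinned to its lowest coverage), classes by the mean of all libraries, the tile minimum taken as a mean over cytosines, and tests with each cytosine weighted equally were chosen after seeing the data. Gains of tiles stayed within 1.5 times of 122 at a coverage minimum of 20 (142 gains and 1 loss), with an upper coverage limit (126), on autosomes (122), without that stretch of chromosome 1 (121), at equal depth (102), in 500 bp tiles (137), with at least 5 cytosines (98), without a minimum difference (141), in the equally weighted test (84) and with an equally weighted minimum (114). Beyond that range, 21 tiles passed a minimum of 25 points, and unmoderated overdispersion, edgeR and limma gave 0. Fisher's exact test on pooled counts, which ignores the spread between libraries, gave 1373 gains and 202 losses (1575). In simulated tiles unmoderated overdispersion, edgeR and limma recovered 4%, 38% and 0% of shifts of 40 points. Those tiles were drawn from the moderated model, so this low recovery does not explain away the 0 calls. Leaving out 1 library gave 52 to 119 called tiles (52 without KO 2, 52 without WT 1, 79 without WT 3), of which 50 to 118 were gains and 0 to 7 losses.

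Single cytosines (8) went to 0 without 80 to 110 Mb of chromosome 1 and without moderation, to 14 with strands summed, to 38133 by Fisher's exact test (25723 gains, 12410 losses), and from 0 to 32 over left-out libraries. Windows (1) went to 0 without moderation, with edgeR and with limma, to 91 by Fisher's exact test, and from 0 to 1 over left-out libraries. Interiors (0) went from 0 to 78 over left-out libraries and to 262 by Fisher's exact test. The class at 90 to 100% methylation reversed to 0.297 points with classes by the mean of all libraries. The mean difference of 0.344 points ranged from 0.280 to 0.409 over left-out libraries and was 4.91 points by reads. Causes not stated here were not tested. Of 709 values of 42 named features under alternatives, 655 kept their side of the threshold, 45 lost the call, 9 gained it and 0 reversed. Most of the 42 were list members not called in the main test, for which staying uncalled was likely. The 655 therefore do not measure how stable the calls were, and all 45 lost calls fell on the few called features.

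The labels do not say whether the replicate numbers pair the libraries. Deviations of same-numbered KO and WT libraries correlated at 0.0279, -0.0175 and -0.0105. KO 1 correlated best with WT 1, while KO 2 and KO 3 correlated best with WT 3 (0.0305) and WT 2 (0.0323). All these correlations were close to none, so they do not exclude that same-numbered libraries shared a day, litter or batch. With the number as a block, 0 tiles, 0 windows, 0 interiors and 0 cytosines were called (the block recovered 44% of simulated 40-point shifts in tiles), camera called 0 lists and the mean difference was 0.344 points. Camera also called 0 lists without each library. The promoter window from the start site, island context and motif analyses, with their alternatives, were not run, for want of strand and sequence.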

Other observations

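The imprinted test below, the equal weights within Vav1 and its coverage, and the splits of cytosines and tiles were chosen after results were seen. The conversion, lineage and variant tests of the tiles were written before their results, as was the depth test, which uses an alternative added once the files had been seen. Imprinted genes hold regions where methylation is intermediate for a known reason. The tiles used here were chosen by their level and by lying in or within 2 kb of such a gene. That imprinting sets their level was not shown for each of them. Around 17 imprinted genes, 42 tiles had a mean methylation of 30 to 70%, and these averaged 44.4% ± 0.644 in KO and 42.3% ± 0.566 in WT (exact permutation p = 0.1). The tile of Grb10, a growth regulator, with 76 cytosines (chromosome 11, 12026001 to 12027000) stood at 44.0% ± 5.4 and 41.1% ± 0.675, that of Zrsr1 with 67 at 36.8% ± 2.54 and 36.8% ± 0.564, and that of Igf2r, a receptor that clears IGF2, with 69 at 31.2% ± 1.62 and 32.5% ± 0.936. Of the 42 tiles, 30 differed by less than 5 points and 3 by at least 10, among them a tile of Gnas with 4 cytosines at 54.9% ± 7.06 and 34.5% ± 6.95.

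KO libraries also gave fewer reads to unmethylated DNA, so methylated molecules might have been read in preference there, which would raise intermediate loci. Imprinted tiles would then be higher by a good part of the median gain of 18.5 points, but their median difference was 1.19 points (quartiles -0.472 to 3.85), close to the 1.52 points of all 9076 tiles at that level. This argues against a preference shared by all loci as the source of gains of that size. It does not exclude a smaller shared preference: library means were 2.05 points higher in KO over the imprinted tiles and 2.31 points over all tiles at that level. A preference that depends on sequence stays open as well.

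The gain in 122 tiles was weighed against 4 technical explanations. Incomplete conversion in KO would need an unconverted share of 37.6% in the median tile, whereas CpG-dense cytosines differed by 0.0652 points. Fewer cells of another lineage in KO would raise that lineage's markers, and the highest median among T cell, myeloid, NK cell and erythroid markers was 1.0 points. The lists also hold regions near 0% in both genotypes, where such a loss would not show: NK cell windows had a WT median of 4.72%. Among T cell windows, 9 were higher and 4 lower, and the lower end of Zap70 rose by 11.1 points. A smaller share of T cells in KO is therefore not excluded. A sequence variant that changes a CpG would act on single cytosines. In the median tile, however, 100% of the cytosines were higher in KO (all of them in 84 tiles, under 80% in 8). The tiles were chosen for a pooled gain, which favours this outcome. Variants that shift the methylation of a whole region would give it too and were not tested. At equal depth 71.3% of the tiles (87) were still called. As a hypothesis, TET2 may keep part of the molecules at these loci unmethylated in WT naive B cells, which 5-hydroxymethylcytosine measured at these tiles would test, though differences of litter, day or cell state between the KO and WT mice, which the labels do not give, were not tested.

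Vav1 (chromosome 17, 57279100 to 57329236) was the sole list member with methylation lower in KO by at least 10 points that passed over its list alone, at -19.9 points between library means. Loss of methylation within it is argued against by the mean over cytosines, which differed by -0.288 points. What differed was coverage: 18 cytosines from 57279064 to 57290718, with pooled methylation of 5.46% in KO and 11.6% in WT, had 2.82 ± 0.152 times the library median in KO and 1.16 ± 0.0366 in WT, a ratio of 2.43 (exact permutation p = 0.1), against 1.2 over the 21 cytosines above them. Extra copies of this part of Vav1 in the KO mice, such as in a transgene, are a candidate explanation, but 44 of 27188 bins of 20 kb had, with complete separation, a ratio above the 2.34 of the bin of Vav1, so that copies cannot be told apart from uneven coverage. In addition, 4 cytosines from 57276851 to 57279454 had 199 to 245 reads in each KO library and were listed in no WT library.

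All 10 splits of the 6 libraries into 3 and 3 were compared, too few for a share under 0.05. The real split called 122 tiles and the highest other 6 (1 of 10 splits reached the real count), 8 cytosines and the highest other 39 (2 of 10), 1 window and the highest other 3 (3 of 10), and 0 interiors and the highest other 0 (10 of 10).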
